A study of Mus musculus and Homo sapiens with 90 samples.

How the data were processed

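Counts were analysed from 90 samples, of which 82 were libraries of a massively parallel reporter assay (MPRA) and 8 were RNA-seq libraries of HepG2 cells. The MPRA set held 46 RNA and 36 DNA libraries. Per the labels' protocols, RNA came from HepG2 cells or mouse liver by column purification, was enriched for poly(A) RNA, treated with DNase and reverse-transcribed with primers specific to the reporter, and DNA was extracted with a plasmid kit. A primer with a molecular identifier (UMI) is named in the protocols, but whether the counts were collapsed by UMI is not stated. Reads amplified by PCR are not independent molecules, so counting intervals and depth limits cover counting error only.

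For the MPRA, the deposited tables hold values in counts, whole numbers per region and library without normalization, made by the authors with BWA against hg38 per the submitters' processing notes. Those notes also name DESeq2 1.42.1 and edgeR 4.0.16. For the RNA-seq, the deposited values are expected_counts, that is, expected counts per gene made by the authors with fastp 0.24.0, STAR 2.5.1b and RSEM 1.2.31 on hg38 per the submitters' processing notes, also without normalization. The annotation behind the gene IDs is not stated. Of the RNA-seq values, 7.97% were not whole numbers, and they were rounded before testing. The 58230 entries with Ensembl gene IDs were kept, and the 649 with numeric IDs and the 97 with spike-in IDs were left out. The spike-in entries held 0 counts in all 8 libraries.

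The 16 MPRA tables cover 5 sub-libraries, which share most negative controls, and 45 test region names were present in all 5. In every table the smallest RNA count was 10, so regions with little or no RNA are not listed and silent regions could not be counted. A column that marks negative controls was present in 12 of the 16 tables. It matched the form of the region names in all 110376 names that carried it, and the class of the remaining 2718 regions was taken from the name. In 1 table, germ-free liver sub-library 3, the replicate numbers in the header differ from those in the sample titles, and the columns were matched by library name.

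Samples were grouped by title. The libraries titled Hep3B carry the genotype p53-null, but their source and cell line entries read HepG2, whereas all other HepG2 samples are p53-WT. They were treated as Hep3B. Mouse liver samples without a treatment entry are called conventional. The batch entry of each MPRA library equals its sub-library, and no label gives a preparation or sequencing batch for germ-free against conventional liver. Library names begin with AML in conventional liver and with GIS in germ-free liver, except the germ-free DNA of sub-library 5, which begins with AML. What these prefixes stand for is not stated. The labels do not say whether replicates came from separate cultures or animals, so p-values measure the spread between these samples.

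Computations used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The comparisons with their tests and thresholds, the naming rules and the alternatives not named below as added were fixed before the data were examined. The comparisons with negative controls, the overlaps between sets, the correlations and the comparison of name prefixes were added later. Each MPRA sub-library was fitted on its own by edgeR's robust quasi-likelihood model with TMM factors. Regions with a mean DNA count of at least 10 were tested for RNA against DNA, which gave the log2 RNA/DNA ratio. Differences between systems were tested as the interaction of RNA/DNA with the system, over regions present in both tables. A region called more active in a system by this test need not be called active there. Benjamini-Hochberg adjustment ran over the regions of all sub-libraries together, with a threshold of 0.05. The standard error (SE) of an edgeR difference, for regions and genes, was its absolute log2 value divided by the square root of the test's F statistic. Intervals of gene differences used this SE. HepG2 and Hep3B have 1 DNA library per sub-library, so their spread comes from the RNA libraries. Negative controls were tested beside the test regions as background, and shares were compared by odds ratios from Fisher's exact test with 95% confidence intervals. A negative control present in several sub-libraries was counted once in each. Such repeats are not independent, so intervals that cover several sub-libraries are narrower than they should be. Regions were also counted above the upper 2.5% and below the lower 2.5% of the negative controls in the same sub-library.

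RNA-seq genes were filtered by edgeR's default expression filter, which left 15023 genes, and were tested with 1 quasi-likelihood model over all 8 libraries, with adjustment within each contrast. Overlaps between gene sets were compared with the number that independent sets would share. Correlations of contrasts that share libraries were set against 20 simulations with no true differences.

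Regions named in the text are those of highest rank by log2 ratio or difference among regions past the threshold with a mean DNA count of at least 50 in each system compared. The rule took 8 per direction. Genes named are those with the largest change in each direction past the threshold, with a mean of at least 5 CPM (read counts scaled to a common total per library) over the 4 libraries compared and no overlap between the libraries of the groups, and the rule took 12 per direction. The files pair neither region IDs nor gene IDs with names, coordinates or sequences, so at most 2 IDs per direction are given. For the same reason the planned tests of promoter share, gene lists and motifs were not run.

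The method was tested on simulated data, with 200 features changed per simulation. At 2-fold and 4-fold it recovered 8% and 77% of changed regions in germ-free against conventional liver (sub-library 1), 29% and 91% in RNA against DNA of HepG2 (sub-library 2), and 89% and 98% of changed genes in the RNA-seq. Of unchanged features it called 0.026%, 0.045% and 0.094%. The real comparisons called far larger shares than were changed here, and the adjusted threshold is then less strict. Recovery and false calls may therefore differ in the real data.

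The alternatives were library-size scaling, DESeq2, no filter or stricter filters on counts, a 2-fold minimum, adjustment within sub-libraries, RNA libraries only, limma with voom weights, only the 4 RNA-seq libraries compared, the replicate number as a block, and each replicate left out in turn. For an MPRA replicate, only its own sub-library was refitted. Scaling on the negative controls, leaving out sub-library 2 or 5, and thinning the germ-free RNA were added after seeing the data. Residuals of DNA and RNA libraries with the same replicate number correlated at -0.046 to 0.035 within sub-libraries, and those of RNA-seq libraries at -0.034 to 0.069 between groups, so the main tests did not use the numbers as pairs. The replicate block did. Where DNA was replicated, the DNA and RNA library of a number were also left out together.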

Results

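Reporter activity was measured by MPRA, in which each candidate regulatory region drives a transcript that identifies it and activity is read as RNA over DNA. The tables held 113094 regions when each sub-library is counted apart, with 105232 distinct names. Of these names, 2048 were negative controls, of which 1674 were present in all 5 sub-libraries. HepG2, a human liver cancer cell line, gave 14 RNA and 5 DNA libraries, with 2 RNA libraries in sub-library 1 and 3 in each other one. Livers of conventional C57BL/6 mice gave 15 RNA and 15 DNA libraries, 4 of each in sub-libraries 1 and 4, 2 in sub-libraries 2 and 3, and 3 in sub-library 5. Livers of germ-free C57BL/6 mice, which lack a microbiota, gave 3 RNA and 3 DNA libraries in each sub-library. Hep3B, another human liver cancer line, was measured in sub-library 2 with 2 RNA libraries and 1 DNA library. RNA-seq covered 4 groups of 2 HepG2 libraries, titled media or with metabolites of a microbial community grown in vitro. The header entries of the media libraries read GAM, so this medium may not be plain culture medium.

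Total counts per RNA library ran from 1720314 to 8202279 in HepG2, 1172822 to 6627375 in conventional liver, 2740171 to 25625463 in germ-free liver and 9394679 to 17696987 in Hep3B. DNA totals ran from 3075432 to 8091318 in HepG2, 2507261 to 6381704 in conventional liver and 4028092 to 9897059 in germ-free liver, and the Hep3B DNA library held 1700473. RNA-seq libraries held 17019364 to 25594588 expected counts. Replicate libraries differed by more than counting error in every group, with a chi-square per degree of freedom of at least 1.71. Between RNA replicates it was 3.595 to 14.7 in HepG2 and 9.48 in Hep3B. In liver RNA it was 8.47 to 66.7 (conventional) and 33.0 to 147.2 (germ-free), against at most 4.80 and 5.62 in liver DNA. Log2 counts of RNA replicates correlated at r down to 0.62 in conventional and 0.65 in germ-free liver. The conventional liver table of sub-library 2 listed 4606 regions, against 22459 in HepG2.

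Test regions were called active more often than negative controls in all 4 systems. In HepG2, 16891 of 90973 test regions (18.6%) had an RNA/DNA ratio above that of the average region and 11752 (12.9%) had one below it, and the highest-ranked named region, EH38D4613310sub4, reached a mean log2 RNA/DNA of 6.64 ± 0.06 (SD, n = 3 RNA libraries). EH38D3705952sub2 followed at 6.39 ± 0.12 (SD, n = 3). In conventional liver, 17476 of 66442 test regions (26.3%) were active and 14359 (21.6%) were low, led by EH38D2916455sub5 at 8.27 ± 0.16 (SD, n = 3) and EH38D2846213sub4 at 8.12 ± 0.21 (SD, n = 4). In germ-free liver, 23826 of 80797 (29.5%) were active and 20054 (24.8%) were low, led by EH38D4202481sub3 at 6.69 ± 0.71 (SD, n = 3) and EH38D5880441sub3 at 6.57 ± 0.08 (SD, n = 3). In Hep3B, 4958 of 20712 (23.9%) were active and 2752 (13.3%) were low, led by EH38D5523586sub2 at 6.09 ± 0.08 (SD, n = 2) and EH38D3725474sub2 at 5.95 ± 0.07 (SD, n = 2). The largest edgeR adjusted p among these 8 regions was 0.00191, for the Hep3B pair, and the files do not pair region IDs with names. In the order named, DNA counts were 81 and 252 for the HepG2 pair and 81 and 53 for the Hep3B pair. Each came from a lone DNA library, so the SD of these pairs leaves out the counting error of the DNA.

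Among negative controls, 4.51% were called active in HepG2, 10.7% in conventional liver, 12.8% in germ-free liver and 9.19% in Hep3B, and 8.85%, 22.0%, 37.4% and 6.92% were called low. In germ-free sub-library 5, 72.7% of negative controls were called either way, against 68.0% of test regions. In the other 4 germ-free sub-libraries negative controls were called less often than test regions, at 30.99% to 51.6% against 40.2% to 60.7%. The odds of an active call were higher for test regions than for negative controls by 4.82 times in HepG2 (95% interval 4.36 to 5.35), 2.98 times in conventional liver (2.74 to 3.25), 2.84 times in germ-free liver (2.63 to 3.07) and 3.11 times in Hep3B (2.65 to 3.67). Except in Hep3B, these intervals count repeated negative controls as independent and are too narrow. Beyond the upper 2.5% of negative controls lay 15.0% of test regions in HepG2, 17.4% in conventional liver, 9.32% in germ-free liver and 12.02% in Hep3B. Below their lower 2.5% lay 5.25%, 3.48%, 2.34% and 4.23%. The median fitted log2 RNA/DNA was 0.01 for test regions and -0.23 for negative controls in HepG2, -0.04 and -0.24 in conventional liver, 0.07 and -0.59 in germ-free liver, and 0.09 and -0.07 in Hep3B.

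**Figure D1:**
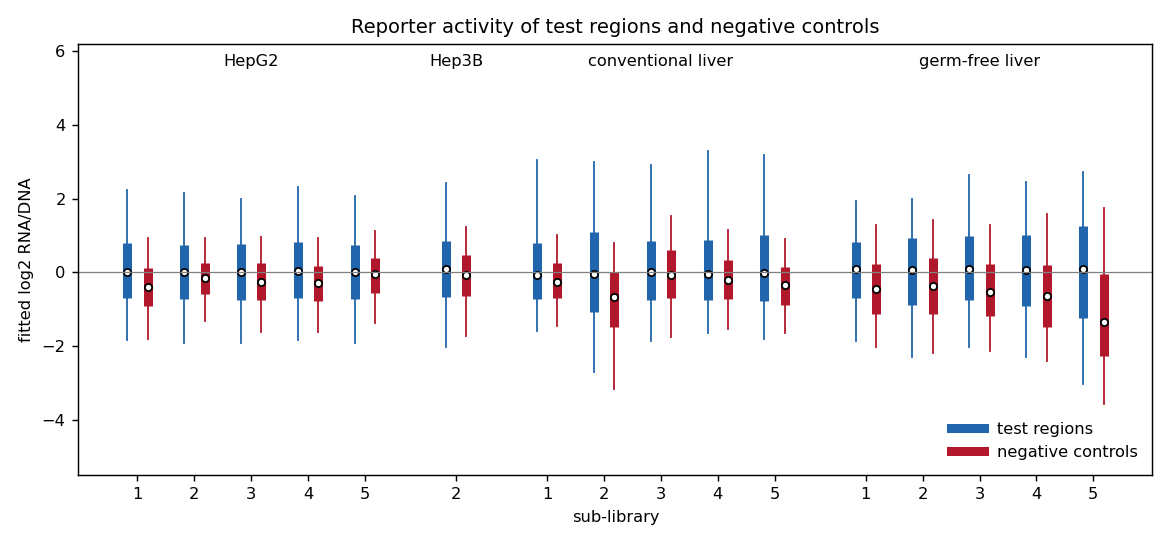
Fitted log2 RNA/DNA (vertical axis) of test regions (blue) and negative controls (red) by system and sub-library (horizontal axis). Circles are medians, thick bars run from the 25th to the 75th percentile and thin lines from the 5th to the 95th; negative controls lie lowest in germ-free sub-library 5, at a median of -1.35.

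The split into active and low regions is relative to the scaling, since TMM sets the average region near 0. Library-size scaling moved the median log2 ratio of all regions to -0.33 in HepG2, -1.01 in conventional liver and -0.31 in germ-free liver, with 12817 active and 18750 low, 9438 and 35392, and 17358 and 26206. Scaling on the negative controls, added after seeing the data, moved the medians to 0.28, 0.27, 0.73 and 0.17, with 21042 active and 7776 low in HepG2, 21744 and 8704 in conventional liver, 38139 and 9759 in germ-free liver, and 1296 and 1249 in Hep3B. A stricter minimum DNA count of 50 left 2088 active regions in Hep3B, whose DNA library was the smallest.

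Active regions overlapped more than independent sets would in the 4 pairs of systems compared. HepG2 and Hep3B shared 3133 active regions where independent sets would share 1219 (odds ratio 13.0, 95% interval 12.02 to 14.03). HepG2 and conventional liver shared 7809 against 3728 (odds ratio 5.87, 5.63 to 6.12), conventional and germ-free liver 8677 against 5246 (3.86, 3.71 to 4.02), and HepG2 and germ-free liver 6907 against 4561 (2.40, 2.316 to 2.497). These intervals treat regions as independent replicates, which they are not. Across regions, which are not independent replicates, fitted ratios correlated at r = 0.74 between the cell lines, and at a median over sub-libraries of 0.64 between HepG2 and conventional liver, 0.59 between conventional and germ-free liver and 0.40 between HepG2 and germ-free liver. Between the livers r ranged from 0.28 in sub-library 5 to 0.70 in sub-library 3.

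The series title asks how the gut microbiota changes regulatory elements, which the comparison of germ-free with conventional liver addresses. Of 52754 test regions in both tables, 10070 were more active and 10886 less active in germ-free liver. EH38D5351023sub5 had a mean log2 RNA/DNA of 4.18 ± 0.48 in germ-free and -2.10 ± 0.70 in conventional liver (SD, n = 3 each), a fitted difference of 6.22 ± 0.50 (SE, edgeR adjusted p 6.61e-07), and EH38D4932940sub5 a difference of 6.16 ± 0.54 (SE, adjusted p 1.44e-06). In the other direction, EH38D4959880sub5 read -4.29 ± 1.11 in germ-free and 5.45 ± 0.23 in conventional liver (SD, n = 3 each), a difference of -9.54 ± 0.62 (SE, edgeR adjusted p 1.14e-07), and EH38D2861744sub5 differed by -9.24 ± 0.50 (SE, adjusted p 3.22e-08). For each of these 4 regions all 3 germ-free RNA libraries lay on one side of all 3 conventional ones, and the files do not pair the IDs with names. The germ-free RNA counts of EH38D2861744sub5 averaged 15.3, near the listing minimum of 10.

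Many negative controls differed between the livers, at a lower share than test regions in each sub-library. Of 3486 negative controls, 368 were higher and 780 lower in germ-free liver, or 32.9%, against 39.7% of test regions (odds ratio 1.34, 95% interval 1.25 to 1.44). The 3486 count a control once per sub-library, so this interval is too narrow. Beyond the upper 2.5% of negative controls lay 3.85% of test regions, from 1.41% to 7.25% by sub-library, and below the lower 2.5% lay 5.32%. Called shares of test regions and negative controls were 37.3% and 29.3% in sub-library 1, 37.0% and 28.6% in sub-library 2, 17.5% and 16.4% in sub-library 3, 41.99% and 28.8% in sub-library 4, and 55.1% and 52.0% in sub-library 5, from which the named regions came. Without sub-library 5, left out after seeing the data, 6081 test regions were higher and 7053 lower. The direction of the split depended on scaling: 17797 were higher and 7066 lower by library size, which moved the median to 0.59, and 14030 were higher and 8124 lower on the negative controls, with a median of 0.35. In sub-library 3, leaving out conventional liver replicate 1 or 2 lowered its 1434 calls to 874 or 927, with a lone conventional library of each kind that is assumed to vary like the rest.

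**Figure D2:**
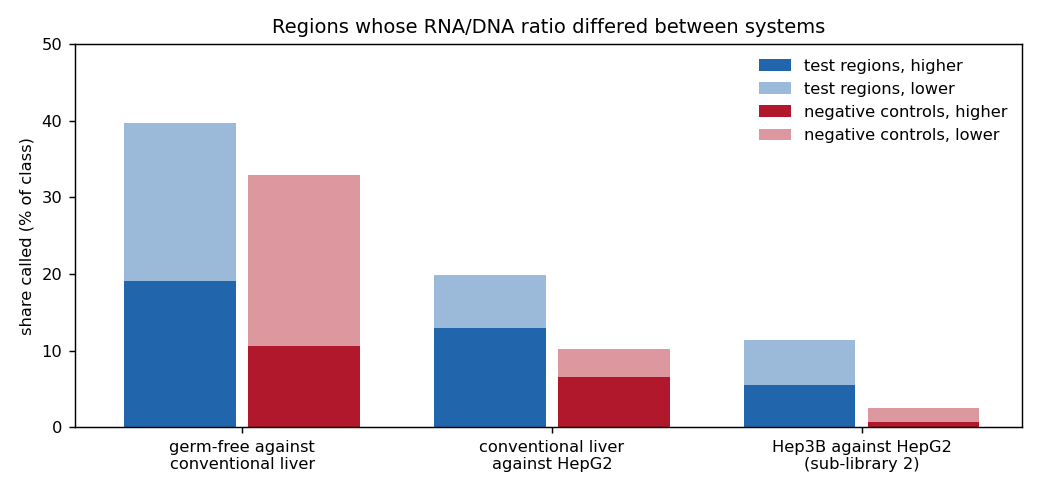
Share of test regions (blue) and negative controls (red) called different between systems, in percent of the class (vertical axis), stacked as higher (dark) and lower (light) in the system named first, for 3 comparisons (horizontal axis). Negative controls were called at 32.9% in germ-free against conventional liver, 10.3% in conventional liver against HepG2 and 2.54% in Hep3B against HepG2.

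Mouse liver and HepG2 are the systems named in the series design, and their comparison sets mouse tissue against a human cancer line in culture. Species, cancer origin and culture cannot be told apart in it, and HepG2 had 1 DNA library per sub-library. Of 60426 test regions, 7853 were more active in conventional liver and 4149 more active in HepG2. EH38D4641825sub4 read 4.74 ± 0.38 in liver (SD, n = 4) and -2.27 ± 0.27 in HepG2 (SD, n = 3), a difference of 7.02 ± 0.29 (SE, edgeR adjusted p 4.32e-10). EH38D4188302sub3 was higher in liver by 6.77 ± 0.61 (SE, adjusted p 5.33e-05). EH38D5721847sub2 read -5.96 ± 1.10 in liver (SD, n = 2) and -0.66 ± 0.09 in HepG2 (SD, n = 3), a fitted difference of -5.20 ± 0.65 (SE, edgeR adjusted p 0.00187), and EH38D5595128sub2 differed by -4.99 ± 0.52 (SE, adjusted p 0.000763). The liver RNA counts of EH38D5721847sub2 averaged 13.5, near the listing minimum of 10, and the files do not pair these IDs with names. Both regions named as lower in liver come from sub-library 2, whose 2 conventional liver RNA libraries correlated at only r = 0.62.

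Of 5465 negative controls 10.3% were called in this comparison, against 19.9% of test regions (odds ratio 2.16, 95% interval 1.98 to 2.37), and 6.48% of test regions lay beyond the upper 2.5% of negative controls and 4.46% below the lower 2.5%. Here too the interval counts repeated negative controls as independent and is too narrow. Library-size scaling turned the split to 4300 higher and 13006 lower in liver, with a median of -0.67, and RNA libraries alone gave 20411 calls. Calls in sub-library 2 rose from 764 to 1841 or 2026 when conventional liver replicate 1 or 2 was left out, which leaves a lone library that is assumed to vary like the rest.

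The labels set HepG2, which is p53-WT, against Hep3B, which is p53-null, in sub-library 2. Of 19768 test regions, 1089 were more active in Hep3B and 1175 more active in HepG2. EH38D5813833sub2 read 5.19 ± 0.06 in Hep3B (SD, n = 2) and 0.48 ± 0.19 in HepG2 (SD, n = 3), a difference of 4.70 ± 0.24 (SE, edgeR adjusted p 4.32e-05), and EH38D3591359sub2 differed by 4.32 ± 0.44 (SE, adjusted p 0.000762). EH38D5784227sub2 read -0.96 ± 0.04 in Hep3B and 5.24 ± 0.04 in HepG2 (SD, n = 2 and 3), a difference of -6.20 ± 0.12 (SE, edgeR adjusted p 3.69e-07), and EH38D3585405sub2 differed by -5.90 ± 0.51 (SE, adjusted p 0.000355). The Hep3B DNA library held only 54 counts of EH38D5813833sub2 and 66 of EH38D3585405sub2. It held 658 of EH38D3591359sub2 and 293 of EH38D5784227sub2. The SD values cover the RNA libraries only, so they leave out the counting error of the DNA. The files do not pair these IDs with names.

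Only 47 of 1854 negative controls (2.54%) were called between the cell lines, against 11.5% of test regions (odds ratio 4.97, 95% interval 3.71 to 6.82), and 8.11% of test regions lay beyond the upper 2.5% of negative controls and 5.52% below the lower 2.5%. The cell lines differ in more than p53, the source entries of the Hep3B samples read HepG2, and each line had 1 DNA library. Library-size scaling gave 1785 higher and 817 lower with a median of 0.39, and scaling on the negative controls 562 and 581. The total was 6975 with RNA libraries alone, 1471 with a DNA count of at least 50, 932 with a replicate block and 1325 without HepG2 replicate 2.

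Negative controls present in several sub-libraries allowed the same sequence to be measured again with other libraries. Across negative controls, which are not independent replicates, their activity correlated between pairs of sub-libraries at a median r of 0.68 in HepG2, 0.56 in conventional liver and 0.70 in germ-free liver. The difference between germ-free and conventional liver of a given negative control correlated at a median r of 0.62 over the 10 pairs, with a range of 0.49 to 0.70. The difference between conventional liver and HepG2 correlated at a median r of 0.55, with a range of 0.30 to 0.65.

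**Figure D3:**
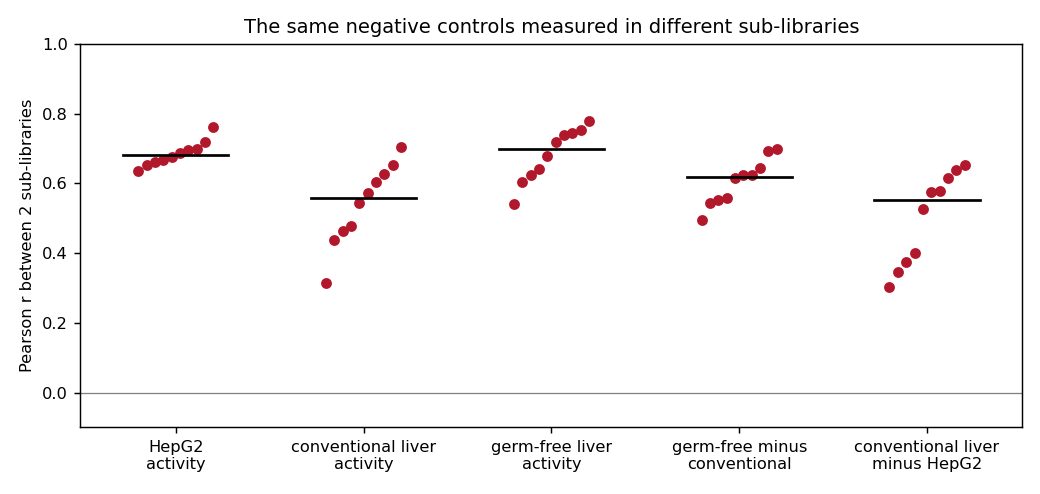
Pearson r across negative controls between pairs of sub-libraries (vertical axis) for activity in 3 systems and for differences between systems (horizontal axis). Each point is 1 of 10 pairs and bars are medians; for germ-free minus conventional liver all 10 lie at 0.49 or above.

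In the RNA-seq, HepG2 cells were kept for 48 h with metabolites of a microbial community, added at 1:32 to the culture medium, or in medium without them. The community had been treated with solvent (metabolites control), with the antimicrobial cyclic peptide wLwKhShK, or with its control diastereomer WlWkHsHK, called diast. Both peptides are written with the same 8 residues, with letter case exchanged at 7 positions. Lower case commonly stands for mirror-image (D) residues, which the labels do not spell out.

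Metabolites of the solvent-treated community changed 52.4% of tested genes against medium, and changes of at least 2-fold were mostly rises. ENSG00000182459.4 stood at 42.1 ± 3.44 CPM with metabolites (SD, n = 2) and at 1 count in both medium libraries together, a ratio of 1654 with a 95% counting interval of 296 to 65391. ENSG00000104833.11 stood at 10.3 ± 0.98 CPM (SD, n = 2) against 3 counts in medium, a ratio of 136 with an interval of 46.2 to 663. ENSG00000165272.15 fell from 12.5 ± 1.17 to 1.49 ± 0.19 CPM (SD, n = 2 each), a log2 change of -3.07 ± 0.25 (SE, edgeR adjusted p 3.24e-09), and ENSG00000213886.3 changed by -2.85 ± 0.19 (SE, adjusted p 1.21e-10). Of 15023 genes tested, 4132 rose and 3737 fell, and 1772 rose and 386 fell past the threshold with at least a 2-fold change. The files do not pair gene IDs with names.

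Metabolites of the peptide-treated community were compared with those of the solvent-treated one, which asks what treating the community changes for the cells. ENSG00000204388.6 rose from 48.9 ± 1.16 to 297.9 ± 23.0 CPM (SD, n = 2 each), a log2 change of 2.61 ± 0.08 (SE, edgeR adjusted p 8.46e-15), and ENSG00000109971.13 rose by 2.60 ± 0.06 (SE, adjusted p 2.01e-16). ENSG00000162543.5 fell from 11.1 ± 1.08 to 0.40 ± 0.11 CPM (SD, n = 2 each), a log2 change of -4.81 ± 0.37 (SE, edgeR adjusted p 3.18e-09). ENSG00000104833.11, named above for its rise with metabolites, changed by -4.49 ± 0.29 (SE, adjusted p 2.96e-10). In all, 3061 genes rose and 3064 fell, and among those with at least a 2-fold change 126 rose and 995 fell.

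Metabolites of the diast-treated community also differed from the solvent control, with fewer genes called. ENSG00000109971.13 rose from 266.4 ± 4.09 to 786.0 ± 8.19 CPM (SD, n = 2 each), a log2 change of 1.56 ± 0.06 (SE, edgeR adjusted p 2.22e-12), and ENSG00000112972.14 rose by 1.54 ± 0.07 (SE, adjusted p 5.81e-12). ENSG00000197405.7 fell from 15.9 ± 1.56 to 2.59 ± 0.46 CPM (SD, n = 2 each), a log2 change of -2.62 ± 0.21 (SE, edgeR adjusted p 2.86e-08), and ENSG00000130487.7 changed by -2.58 ± 0.20 (SE, adjusted p 2.43e-08). In all, 1566 genes rose and 1606 fell, and 44 rose and 217 fell by at least 2-fold. Leaving out any 1 of the 4 libraries gave 1763 to 1907 calls, the lowest without metabolites control replicate 2, and library-size scaling gave 1196 higher and 1864 lower.

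The direct comparison of the peptides, at the same dilution and time, gave 1286 genes higher and 1380 lower with peptide than with diast metabolites, and 34 higher and 267 lower by at least 2-fold. ENSG00000182459.4, which metabolites had raised, stood at 3.34 ± 1.08 CPM with peptide and 27.7 ± 2.58 CPM with diast metabolites (SD, n = 2 each), a log2 difference of -3.03 ± 0.17 (SE, edgeR adjusted p 3.52e-10). ENSG00000101210.11 stood at 7.18 ± 0.90 and 44.1 ± 3.12 CPM (SD, n = 2 each), a difference of -2.62 ± 0.16 (SE, edgeR adjusted p 2.45e-07). ENSG00000252010.1 was higher with peptide by 1.55 ± 0.17 (SE, adjusted p 2.73e-06). ENSG00000263934.4 was higher by 1.35 ± 0.24 (SE, edgeR adjusted p 0.029), a call that was lost without any 1 of the 4 libraries or with those 4 libraries alone, at adjusted p 0.0528 to 0.118. The total fell to 1037 calls without peptide replicate 1, 1143 without diast replicate 1 and 1304 without diast replicate 2, and was 2235 without peptide replicate 2.

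Of genes that rose with peptide metabolites against the solvent control, 1229 also rose with diast metabolites, and 1345 fell with both. Both contrasts use the same control libraries, which alone raises such an overlap. Across genes, which are not independent replicates, the changes correlated at r = 0.75, against 0.51 in simulations with no true difference. The covariance, which is not divided by the spread of the changes, was 0.148 against 0.023 in those simulations. Of 6711 genes called with either peptide, 2358 differed between the peptides and 4353 were not called different. For 3633 of those 4353 the 95% interval of the difference lay within 2-fold. Of 3539 genes called with the peptide alone, 1420 differed between the peptides when tested directly.

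Genes that metabolites raised were over-represented among those lower with peptide than with diast metabolites. Over the 1772 genes that metabolites raised by at least 2-fold, the median log2 difference from medium was 2.00 with the solvent control, 1.68 with diast and 1.22 with peptide metabolites, and 80.9% were lower with peptide than with diast. These genes were chosen by their rise with the solvent control, which by itself favours its first place. The order of peptide and diast does not rest on that choice. Of the 4132 genes that rose with metabolites, 720 were called lower with peptide than with diast where independent sets would share 379.6, an odds ratio of 3.27 (95% interval 2.92 to 3.67) between contrasts with no library in common, and 213 were called higher. Of the 3737 that fell, 604 were called higher with peptide against 319.9, an odds ratio of 3.00 (2.66 to 3.37). Genes are not independent units, so these intervals are narrower than they should be. The contrasts also share 1 estimate of spread over all 8 libraries, so the number for independent sets is only a rough reference. Compared with medium itself, 4246 genes were higher and 3683 lower with peptide metabolites, and 4239 and 3676 with diast metabolites. By at least 2-fold, 1198 were higher and 689 lower with peptide, and 1546 and 579 with diast metabolites.

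**Figure D4:**
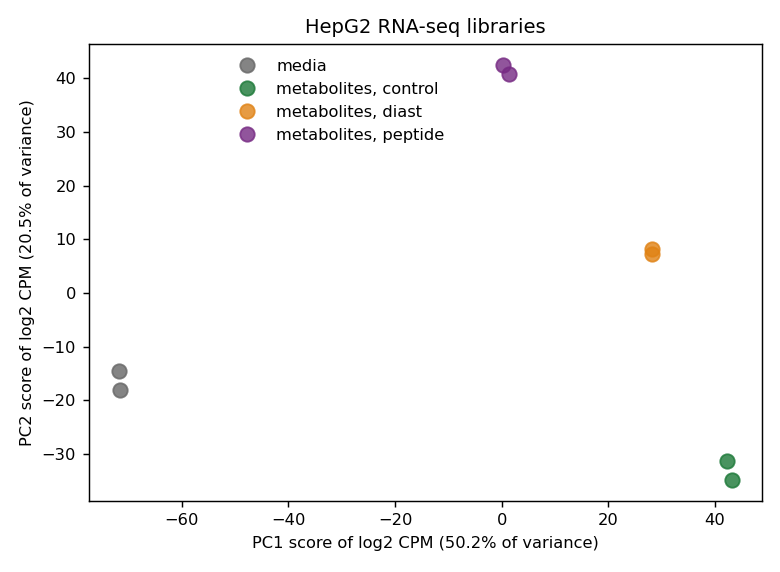
Principal component scores of log2 CPM of the 8 HepG2 RNA-seq libraries, PC1 (50.2% of variance, horizontal axis) against PC2 (20.5%, vertical axis), 1 point per library, coloured by group. On PC1 the medium libraries lie at -71.7 and -71.6, peptide at 0.17 and 1.43, diast at 28.1, and metabolites control at 42.2 and 43.2. On PC2 medium lies at -14.5 and -18.0, peptide at 42.5 and 40.8, diast at 7.20 and 8.14, and metabolites control at -31.3 and -34.8.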

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

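Of the tests in this part, the correlation of negative controls between sub-libraries, the thinning of the germ-free RNA and the odds ratio between the peptides were chosen after the result was seen. In conventional liver sub-library 1, DNA replicate 1 held 6381704 counts, farther from the other 3 than their spread by Dixon's test, which was applied to 6 sets of 4 values (the totals of 4 groups of libraries and the ratios of 2 named regions) and picks about 1 in 20 by chance. Differences between systems or treatments, each by a test of the difference itself, were 20956 test regions between germ-free and conventional liver, 12002 between conventional liver and HepG2, 2264 between Hep3B and HepG2, and 2666 genes between peptide and diast metabolites.

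In germ-free against conventional liver, 32.9% of negative controls were called, against 39.7% of test regions. Chance differences between animals or pools that each served a single sub-library would leave the sub-libraries uncorrelated, but the difference of a given negative control correlated between sub-libraries at a median r of 0.62. Animals or preparations shared between sub-libraries could make chance differences correlate too. The labels do not say whether animals were separate, so that case stays open. Deeper germ-free RNA libraries are argued against by thinning them to the conventional depth, after which 33.0% were called. A bias that follows representation in the DNA pool stays open: the median absolute r with log2 DNA count was 0.0962, just under the bound of 0.1 set beforehand, but sub-libraries ranged from -0.18 to 0.29, and the demand that each of them lie under the bound was added after this was seen. Germ-free status itself, acting on the negative controls, and a preparation batch that the labels do not give cannot be told apart, so the calls may reflect either, and neither was tested.

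Of 4132 genes that rose with metabolites, 720 were called lower and 213 higher with peptide than with diast metabolites, an odds ratio of 3.27 for lower calls. Control libraries shared between contrasts would not produce this, since the metabolite contrast and the peptide against diast contrast have no library in common. Deeper peptide libraries are argued against by thinning all 8 libraries to the smallest total, which gave an odds ratio of 3.19. A candidate explanation is that treating the community with the peptide lowered the metabolites that act on HepG2, but metabolite levels were not analysed here. It would cover only the weaker metabolite response. On PC2 the peptide libraries lay at 42.5 and 40.8, beyond both medium (-14.5 and -18.0) and metabolites control (-31.3 and -34.8). Their profile was thus not simply intermediate between medium and metabolites control. With 2 libraries per group, differences between the metabolite preparations also stay open, untested.

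Regroupings of the libraries were counted over sub-libraries with at least 3 libraries per group. Between the livers, the RNA and DNA library of a replicate number were moved together. In each comparison only 1 of 100 splits, the real one, called as many test regions. The splits recombine 80, 50 and 80 single fits for conventional liver, germ-free liver and between the livers. For activity the outcome was fixed beforehand, because RNA and DNA libraries differ in kind, so it says nothing about chance. Between the livers, the real split called the most of 35, 35 and 10 splits in sub-libraries 1, 4 and 5. That shows that these libraries differ as groups, not why. Splits that mix RNA with DNA libraries, or the livers, put the real difference into the spread, so their low counts do not say how many single calls arose by chance. The real splits called 27070 regions in conventional liver, 43880 in germ-free liver and 18346 between the livers, and the highest others called 9032, 25142 and 7626. Those high draws held the real split of at least 1 sub-library, which 17, 37 and 17 of the 100 did, and the median of the other splits was 0 in each comparison. Within single sub-libraries, the highest other split between the livers called 10 regions in sub-library 1, 195 in sub-library 4 and 0 in sub-library 5, against 5197, 5481 and 7609.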

How the results depend on the processing

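Scaling on the negative controls, leaving out sub-library 5 and thinning were chosen after the result was seen. Of 89 alternative counts, 75 lay within 1.5 times the reported one, as did 110 of 118 counts with 1 replicate left out. Most of these 118 are totals over 5 sub-libraries with only 1 of them refitted, so they could hardly move 1.5 times. Within the refitted sub-library some counts moved farther, as given here and above. A further 8 leave-outs left no residual degrees of freedom and gave no test. Of 433 values for 36 named results, each a region or gene in 1 comparison, 428 kept direction and call, 5 lost the call, all for ENSG00000263934.4, and 0 reversed. The other 14 counts were as follows, and except for the 2-fold minimum, the DNA minimum and the left-out samples, which test less or ask more by construction, the cause was not tested. Library-size scaling gave 9438 active regions in conventional liver. Scaling on the negative controls gave 38139 in germ-free liver, 1296 in Hep3B and 1143 differences between Hep3B and HepG2. A DNA count of at least 50 gave 2088 active regions in Hep3B and 1471 differences between Hep3B and HepG2. Without sub-library 5, 13134 test regions differed between the livers. RNA libraries alone gave 20411 differences between conventional liver and HepG2 and 6975 between Hep3B and HepG2, and a replicate block gave 932 for the latter. A 2-fold minimum left 2158 genes for metabolites against medium, 1121 for peptide and 261 for diast against the solvent control, and 301 between the peptides. Leaving out 1 replicate at a time gave 1325 to 2963 for Hep3B against HepG2 (lowest without HepG2 replicate 2), 1763 to 1907 for diast against the solvent control (each of the 4 libraries), and 1037 to 2235 between the peptides (lowest without peptide replicate 1, and 1143 and 1304 without diast replicates 1 and 2). With the replicate number as a block, the other counts were 16461 and 21504 active regions in conventional and germ-free liver, 19228 differences between the livers, and 8196, 6576, 3706 and 3404 genes in the 4 contrasts in the order above. Within sub-libraries, active calls in germ-free liver fell from 4143 to 2456 in sub-library 1 and from 4158 to 2688 in sub-library 4 without replicate 3. Promoter share, gene lists and motifs were not run. Simulated 2-fold changes between the livers, with 200 of 15442 regions changed, were recovered at 8% in sub-library 1. The real comparison there called 37.3% of test regions, so the 8% need not hold for it. Germ-free RNA replicates in that sub-library differed by a chi-square per degree of freedom of 33.0 to 63.4. Over all sub-libraries, thinning the germ-free RNA gave 20815 calls against 20956. Regions with RNA counts under 10 are not listed.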

Other observations

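Some test regions were present in several sub-libraries, and the values given here were chosen after they were seen. Relative to the median negative control of each sub-library, EH38D3158852 had a mean log2 RNA/DNA of 3.29 ± 0.30 in HepG2 (SD over 5 sub-libraries, limma adjusted p 6.23e-08). EM10D2546617 was higher in germ-free than in conventional liver by 2.57 ± 0.71 (SD over 4 sub-libraries, limma adjusted p 0.00103), and EH38D5698024 by 2.46 ± 1.01 (SD over 5 sub-libraries, limma adjusted p 0.00103). EM10D2955686 differed by -1.35 ± 0.67 (SD over 4 sub-libraries, limma adjusted p 0.0293). Of the 14 test regions present in at least 4 sub-libraries, 5 were called higher and 1 lower in germ-free liver, and of 308 such negative controls 65 and 27. The 308 themselves lay at a median of 0.33 above the reference, the median of all negative controls, which favours higher calls. In the main test, with TMM factors, 368 negative controls were higher and 780 lower, the opposite split.

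Nearly all test region names begin with EH38D or EM10D, and the files do not say what the prefixes stand for. In conventional liver the mean log2 RNA/DNA of 34 EM10D regions lay below that of EH38D regions by a difference of -0.63 (permutation p 0.014, adjusted p 0.0489 over 7 comparisons), and in germ-free liver that of 35 lay below by a difference of -0.56 (permutation p 0.0213, adjusted p 0.0497). Between conventional liver and HepG2 the EM10D regions differed from the EH38D regions by -0.66 (permutation p 0.00207, adjusted p 0.0145). In HepG2 the difference was 0.13 (permutation p 0.542, adjusted p 0.636). The other 3 comparisons were not called, with adjusted p of 0.149 to 0.987. EM10D values are means over up to 5 sub-libraries, which EH38D values mostly are not, and the comparison was chosen after the names were seen.

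Across genes, which are not independent replicates, the changes with peptide and with diast metabolites against the shared solvent control correlated at r = 0.75, where libraries with no true difference gave 0.51 through the shared control. The change with metabolites against medium correlated with the change with peptide metabolites at r = -0.53, near the -0.51 of simulation. With the change with diast metabolites r was -0.38, against -0.50. The covariances of these 2 pairs were -0.202 and -0.102, against -0.023 in simulation. The change with metabolites and the difference between the peptides, which share no library, correlated at r = -0.40, where simulation gave 0.00079.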
